A study of Homo sapiens with 12 samples.

How the data were processed

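The series holds 12 libraries in 6 groups of 2, HEK293T cells with a control hairpin or either of 2 hairpins against YY1, each without and with PDS. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with the NEBNext Ultra II RNA kit. The dose and duration of PDS and the way knockdown was induced are not given in the sources used here, nor is whether libraries of a group came from separate cultures. Groups and replicate numbers were taken from the sample titles.

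The authors deposited 1 table of TPM with a column per library and 60623 genes by Ensembl identifier and symbol. The submitters' processing notes name HISAT2, featureCounts and DESeq2 with the builds hg19 and hg38, without versions or the role of each, so which build and annotation the counts rest on is not given in the sources used here. Of the identifiers, 58516 (96.5%) were found in GENCODE 29, whose GRCh38 coordinates are printed as a reference and whose build may differ from the one the authors counted on. A symbol was carried by more than 1 row for 1213 symbols, and genes were followed by identifier.

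TPM keep no depth, but whole reads could be recovered from them. For each of the 30762 genes above 0 in at least 1 library, the ratios between libraries were matched to whole numbers of reads, with a tolerance of 0.0001 reads, and this worked for 100% of them. The gene length that the reads imply was equal to the annotated exon length for 19019 of 29888 genes with one (63.6%), and the reads of 480 genes were multiplied by a whole factor to meet that length. A gene whose reads share a common factor in every library can still be too low by that factor. Recovered totals were 386097 and 470526 reads in shCtrl and 544766 to 2072851 in the other groups, so that 1 read in the shallowest library stood for 4.71 times the TPM it stood for in the deepest. These depths are low for a transcriptome, and at 0 to 3 reads in a group a fitted fold change depends on the pseudocount and is not a size. Where a group had 0 reads, the fold was bounded against a floor of 3 reads over the group. With 1 to 3 reads, the ratio of pooled reads scaled by library size was given with an exact 95% interval of counting error. No fold was given where both sides held 3 reads or fewer or the bound was below 1.

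By share of TPM, 7SL RNA took 17% to 27.2% and ribosomal RNA loci 7.95% to 18.6% of a library, and protein-coding genes 48.2% to 59.9%. By share of reads, protein-coding genes took 87.9% to 91.6%. Mitochondrially encoded protein genes (13 genes) were listed at 0 in every library, so nothing is said of them. Histone genes and other near-identical copies can exchange reads, and nothing in the sources says whether counting used strand, so antisense and overlapping genes are uncertain too.

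The main test was limma (3.58.1, in R 4.3.3) on log2(TPM + 1), with the mean-variance trend and without the robust option. Genes with a TPM of at least 1 in at least 2 libraries were tested (22672). All 12 libraries entered 1 fit with a coefficient per group, which shares 1 unweighted estimate of the spread despite unequal depths. Contrasts were both hairpins averaged against shCtrl without PDS and with PDS, each hairpin alone, the hairpins against each other, PDS against none in control cells and in knockdown cells, the interaction of both, and the averages over PDS and over cells. P-values were adjusted by the method of Benjamini and Hochberg within a contrast, with a threshold of 0.05, and are two-sided.

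Gene lists of pathways, complexes, RNA classes and markers of other cell types (45 lists) were written down with the design, and the 42 with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a contrast. The protocadherin clusters and endothelial markers had 4 tested members each and were not tested. Camera compares a list with all other genes. It was repeated with a correlation estimated per list, and the counts of called members are given over all genes and over the list alone.

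The tests, the lists, the naming rule and the alternatives in this paragraph were fixed before the data were examined. Genes named in the text were YY1, then for each of the 4 main comparisons the 12 protein-coding genes with the largest increase and the 12 with the largest decrease among those that passed. They had to have a mean TPM of at least 5 in a group compared, the same sign for both hairpins and no overlap between the libraries of the sides. The interaction, whose sides cannot overlap in that sense, and the hairpin difference had 6 each way, and where none passed 5 each way are given as values. Up to 4 called members per list and all called oncogenes with a promoter G-quadruplex could be named, with members needed to show that a list did not move as its name says. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without short noncoding RNA, ribosomal RNA and histone genes, no trend, the robust option, only the groups compared, the replicate number as a block, and each library left out in turn.

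Further tests were added after the depth difference had been seen. Recovered reads of 12302 genes with at least 10 reads in at least 2 libraries were tested with voom of limma, also on the genes of the TPM filter and with quantile normalization. Reads were thinned at random to the total of the shallowest library and tested like the TPM. Knockdown without and under PDS, which share no library, were overlapped as well, and so were comparisons that take 1 shCtrl library each. The overlap of a hairpin against shCtrl with PDS in cells of the other hairpin, also without a shared library, had been planned.

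The gene tests on log2 TPM, on reads with voom and on thinned reads were tested on simulated data at the real depths in the 4 main comparisons, with a dispersion of 0.00497 from the replicate pairs and 200 changed genes, 100 at each of 2-fold and 4-fold. The changed genes were drawn from the 12302 genes with at least 10 reads in at least 2 libraries. Recovery among the remaining genes, which have fewer reads, was not measured. For knockdown without PDS the main test recovered 36% of 2-fold and 83% of 4-fold changes, with 146 other genes called among 22639. Voom on reads recovered 49% and 85% with 13 others among 12144, and thinned reads 9% and 42% with 59 others among 19987. List tests, motif tests, other scalings, the interaction and the hairpin contrasts were not tested with changed genes. For PDS in control cells the main test recovered 19% and 65%, with 99 other genes called. For PDS in knockdown cells it recovered 43% and 79% with 71 others, and for knockdown under PDS 39% and 76% with 52 others. With no change simulated, 20 draws gave a median of 61.5 calls and a highest of 132 for knockdown without PDS in the main test, and a median of 1 with voom.

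Planned tests of G-quadruplex and YY1 motifs around transcription starts need a genome sequence, which is not among the sources used here, and were replaced by tests on the first bases of annotated transcripts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for read recovery, motifs and figures.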

Results

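Gene expression was measured in 12 libraries of total RNA, depleted of ribosomal RNA, from HEK293T cells, a transformed line derived from human embryonic kidney. The libraries formed 6 groups of 2. Cells carried a control short hairpin RNA (shCtrl) or either of 2 hairpins against YY1 (shYY1-1 and shYY1-2), each without and with pyridostatin (PDS). PDS is a small molecule that binds and stabilises G-quadruplexes, folded structures of guanine-rich DNA and RNA. YY1 is a zinc-finger transcription factor that binds promoters and enhancers. The design asks how expression responds to loss of YY1, to a ligand that occupies G-quadruplexes, and to both together. Values are TPM for 60623 genes, given as mean ± SD of the 2 libraries of a group. Fold changes are on the log2(TPM + 1) scale with their SE, which understates the change of low genes. Coordinates are those of GENCODE 29 on GRCh38. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

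The number of reads behind the values differed between groups. The shCtrl libraries held 386097 and 470526 reads, the shCtrl+PDS libraries 763000 and 544766, and the shYY1-1 libraries 2072851 and 1896331. The other groups lay between these, with 1929588 and 1781482 reads in shYY1-2, 1672268 and 1071666 in shYY1-1+PDS, and 1440089 and 1255555 in shYY1-2+PDS. Genes with a value above 0 numbered 14803 in shCtrl replicate 1 and 22048 in shYY1-1 replicate 1. Replicates differed from each other more than counting error alone allows, with a chi-square per degree of freedom from 1.17 to 1.39 in the 6 pairs, against 1.19 to 1.85 in 8 pairs of different hairpins in the same PDS state, which overlap the replicates, and 1.85 to 5.72 in the 52 other pairs between groups.

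**Figure D1:**
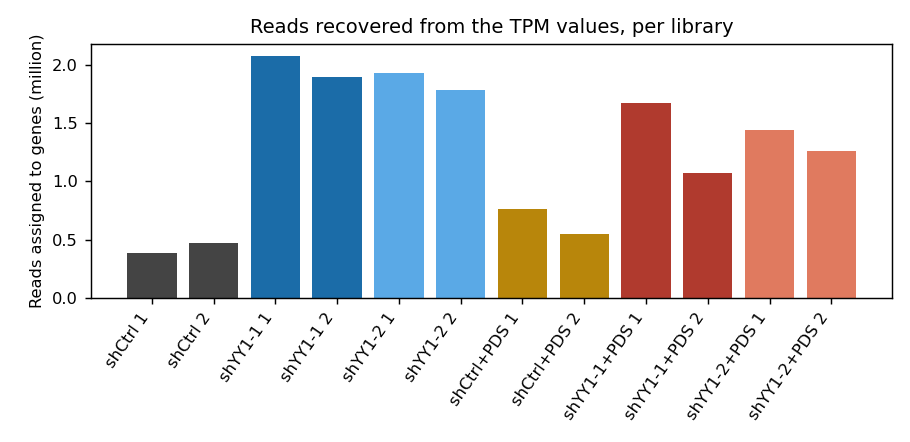
Reads recovered from the TPM values of each of the 12 libraries, by group. The 2 shCtrl libraries (386097 and 470526 reads) were the shallowest.

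YY1 (ENSG00000100811, chromosome 14, 100238298 to 100282792, plus strand) was examined in every library first, as the target of both hairpins. Its TPM were 78.3 and 75.6 in the shCtrl libraries, 25.1 and 25.6 in shYY1-1, and 22.9 and 23.1 in shYY1-2. With PDS they were 67.6 and 58.8 in shCtrl+PDS, 16.4 and 20.9 in shYY1-1+PDS, and 20.4 and 23.2 in shYY1-2+PDS. YY1 fell 3.1-fold with knockdown, the mean over both hairpins (log2 fold change -1.63, SE 0.12, limma adjusted p = 0.00014), by 1.56 on the log2 scale with shYY1-1 and by 1.70 with shYY1-2. Under PDS the difference between the hairpins against YY1 and the control hairpin was -1.60 (SE 0.12, limma adjusted p = 0.00098). PDS itself gave YY1 changes that did not pass the test, -0.28 (SE 0.14, limma adjusted p = 0.31) in control cells and -0.25 (SE 0.10, limma adjusted p = 0.29) in knockdown cells.

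**Figure D2:**
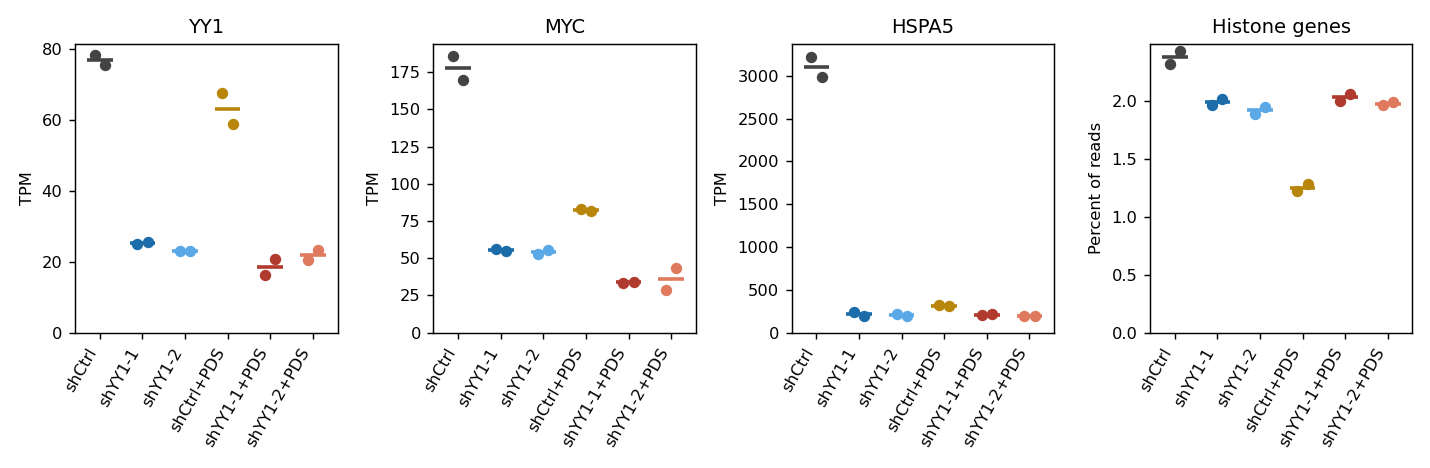
TPM of YY1, MYC and HSPA5 and the percent of reads in histone genes in each library (points) with group means (bars). YY1 lay at 58.8 TPM or above in the 4 libraries with the control hairpin and at 25.6 or below in the 8 with a hairpin against it, and HSPA5 had a mean of 3100 TPM in shCtrl against 316 or less in every other group.

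The comparison of both hairpins against YY1 with the control hairpin, without PDS, addressed what loss of YY1 does to expression (4 libraries against 2). HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330, minus strand), the main chaperone of the endoplasmic reticulum lumen, had 3100 ± 167 TPM in shCtrl and 216 ± 29.3 and 207 ± 12.3 TPM in shYY1-1 and shYY1-2 (n = 2 each). It fell 14.6-fold (log2 fold change -3.87, SE 0.09, limma adjusted p = 6.4e-07). LGALS3BP (ENSG00000108679, chromosome 17, 78971238 to 78980109, minus strand), a secreted glycoprotein, fell 20-fold from 309 ± 3.59 TPM (log2 -4.32, SE 0.22, limma adjusted p = 5.0e-05). In the opposite direction NEFM (ENSG00000104722, chromosome 8, 24913012 to 24919098, plus strand), the medium neurofilament chain, rose 17.1-fold from 10.1 ± 0.494 TPM to 196 ± 0.801 and 182 ± 16.9 TPM (log2 4.10, SE 0.16, limma adjusted p = 1.7e-05). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand), whose promoter holds a well studied G-quadruplex, fell 3.2-fold from 178 ± 11.5 TPM to 55.8 ± 1.03 and 53.8 ± 1.93 TPM (log2 -1.68, SE 0.14, limma adjusted p = 0.00025).

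Among the 12 genes named for the largest decreases, besides HSPA5 and LGALS3BP, were HERPUD1, a component of endoplasmic-reticulum-associated degradation (9.7-fold lower), CHAC1, an enzyme that degrades glutathione (16.9-fold lower), CTH, which makes cysteine from cystathionine (log2 -2.83, SE 0.43), and ASNS, asparagine synthetase (log2 -2.64, SE 0.54, limma adjusted p = 0.011). The others were FBXL16 (11.3-fold lower), RAB39B (log2 -3.09, SE 0.39), and CT45A10 and CDRT15, whose reads were too few for a fold. The histone genes HIST1H2AE (6.83-fold lower, from 1080 ± 84.5 TPM) and HIST1H2BG (log2 -2.71, SE 0.21) were also among them, with reads that may be shared with near-identical copies. RASL10B, a Ras-like small GTPase, rose 13.3-fold to 68.1 ± 9.7 TPM in shYY1-1 (log2 3.73, SE 0.39, limma adjusted p = 0.00067). Of the other genes named for the largest increases all had few reads in the shallow shCtrl libraries. The bounds and 95% intervals given for such genes cover counting error only, and the floor is 3 reads over a group. LTBR, the lymphotoxin beta receptor (ENSG00000111321, chromosome 12, 6375045 to 6391571, plus strand), had 0 reads in shCtrl and was at least 8.81-fold higher with knockdown. Also at 0 reads in shCtrl, SLC25A43 was at least 4.83-fold higher, MSLNL at least 3.61-fold, CD70 at least 2.35-fold and PRRX2 at least 2.06-fold, while C6orf226 was given no fold. RAB39A had a read ratio of 19.9 (3.52 to 791), RAB32 of 14.5 (2.55 to 577), VAMP8 of 11.1 (1.94 to 442) and BEX1 of 8.62 (2.34 to 71.9).

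Genes of the endoplasmic reticulum and amino acid stress pathways fell together with knockdown. Of 21 genes of the unfolded protein response 15 fell and 1 rose (15 and 1 adjusted over the list alone). Their median log2 change was -1.13, or -1.61 relative to all genes (camera of limma, adjusted p = 1.5e-26, and adjusted p = 0.038 with an estimated correlation). SDF2L1 (log2 -2.39, SE 0.14) and PDIA6 (log2 -1.86, SE 0.11) were among them. Of 34 targets of ATF4, the transcription factor of the amino acid and integrated stress response, 26 fell and 1 rose (29 and 1 adjusted over the list alone). The median was -1.05 (camera of limma, adjusted p = 2.6e-40, and adjusted p = 0.038 with an estimated correlation). MYC target genes fell in 16 of 34 members and rose in 3 (19 and 3 adjusted over the list alone, median -0.34, camera of limma adjusted p = 2.1e-12). SLC7A5, an amino acid transporter (log2 -1.39, SE 0.07), and HK2, a hexokinase (log2 -1.31, SE 0.11), were among them. Ribosome biogenesis genes fell in 10 of 46 members and rose in 2 (12 and 2 adjusted over the list alone, median -0.23, camera of limma adjusted p = 4.0e-11). RRP12 was at -0.89 (SE 0.11) and BOP1 at -0.78 (SE 0.07). For these last lists the call was lost with an estimated correlation (adjusted p = 0.27 for MYC targets and adjusted p = 0.24 for ribosome biogenesis) on log2 TPM. On reads both passed with it (camera of limma, adjusted p = 0.0022 for each), with 21 members lower and 1 higher in either list.

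Other lists stood below the remaining genes, on log2 TPM without a uniform direction among their members. Of 82 cytosolic ribosomal protein genes 15 fell and 11 rose (21 and 16 adjusted over the list alone). RPL12 was at -1.03 and RPS27 at 1.10. Their median was -0.01 (camera of limma, adjusted p = 1.9e-06, and adjusted p = 0.42 with an estimated correlation). Of 68 replication-dependent histone genes 13 fell and 13 rose (19 and 15 adjusted over the list alone). The list median was 0.03 and the mean 0.14, but the median was -0.10 with genes at 0 reads set to their bound. The test pointed down (camera of limma, adjusted p = 0.00036, and adjusted p = 0.39 with an estimated correlation), and turned up under quantile normalization (adjusted p = 0.60). The 47 replication and E2F target genes (11 fell, 6 rose, median 0.02) and the 19 glycolysis genes (4 fell, 2 rose, median 0.09) had the same counts adjusted over the list alone. They also had a positive median and a downward test (camera of limma, adjusted p = 0.00022 and 0.0093, and adjusted p = 0.39 for each with an estimated correlation). PFKL, phosphofructokinase of liver type, fell (log2 -1.52, SE 0.10). On reads most called members of these lists fell, 34 against 4 ribosomal protein genes (median -0.17), 25 against 8 histone genes (-0.30), 16 against 2 replication and E2F targets (-0.15) and 6 against 1 glycolysis gene (-0.09). With an estimated correlation on reads their tests gave adjusted p = 0.0022, 0.070, 0.038 and 0.037 (camera of limma).

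Mitotic genes rose in 36 of 52 members and fell in 0 (40 and 0 adjusted over the list alone). Their median was 0.71, or 0.24 relative to all genes (camera of limma, adjusted p = 1.6e-09, and adjusted p = 0.27 with an estimated correlation). ASPM, a spindle-pole protein (log2 2.06, SE 0.09), and MKI67, the proliferation antigen (log2 1.75, SE 0.09), were examples. Genes of the TGF-beta response and epithelial-mesenchymal transition rose in 12 of 25 members (15 adjusted over the list alone, median 0.90, or 0.83 with genes at 0 reads set to their bound). FN1, fibronectin, was at 2.06 (SE 0.24). Immediate early genes rose in 14 of 31 members and fell in 1 (19 and 1 adjusted over the list alone, median 1.09, or 0.91 with bounds). JUNB, a Jun-family transcription factor, was at 2.11 (SE 0.20). Neuronal genes rose in 12 of 23 members (13 adjusted over the list alone, median 1.09, or 0.71 with bounds). STMN3, a stathmin, was at 2.03 and INA, a neuronal intermediate filament, at 1.99. Adjusted p-values of camera for these 3 lists were 0.00026, 0.0013 and 0.0023 (adjusted p = 0.27, adjusted p = 0.27 and adjusted p = 0.13 with an estimated correlation). Their medians relative to all genes were 0.42, 0.61 and 0.61. Lysosome genes rose in 22 of 42 members (23 adjusted over the list alone, median 0.65, or 0.64 with bounds). Cohesin and CTCF genes rose in 10 of 16 (10 adjusted over the list alone, median 0.64) and heat shock genes in 11 of 18 (11, with 1 lower, adjusted over the list alone, median 0.59). These 3 had camera adjusted p = 0.00045, 0.0025 and 0.0021, and adjusted p = 0.39 for each with an estimated correlation. STAG2, a cohesin subunit, was at 1.08 (SE 0.12), MAP1LC3B, an autophagosome protein, at 1.25 (SE 0.14) and HSPB1, a small heat shock protein, at 1.39 (SE 0.19). On reads with an estimated correlation the lysosome list passed (camera of limma, adjusted p = 0.038) and the other 6 lists of this paragraph did not (adjusted p from 0.057 to 0.37).

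Lists closest to the subject of the study did not stand apart from the other genes with knockdown. Of 23 oncogenes with a promoter G-quadruplex 11 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.72, or 0.52 with bounds, camera of limma adjusted p = 0.28). Besides MYC, VEGFA fell (log2 -0.88, SE 0.13). MET (1.13), ZEB1 (1.12), PIM1 (1.10), NRAS (0.97), HIF1A (0.94), YAP1 (0.94), RB1 (0.77), HSP90AA1 (0.52) and MYBL2 (0.33, and -0.01 under median-of-ratios scaling) rose. PDGFA, with 0 reads in shCtrl, was at least 2.64-fold higher. Helicases and proteins that bind G-quadruplexes rose in 7 of 31 members and fell in 3 (10 and 4 adjusted over the list alone, median 0.24, camera of limma adjusted p = 0.84). TOP2A, a DNA topoisomerase, was at 1.18 (SE 0.10). YY1 and its partner proteins rose in 8 of 24 members and fell in 4 (9 and 4 adjusted over the list alone, median 0.28, camera of limma adjusted p = 0.83). RYBP, a Polycomb partner of YY1, was at 1.13 (SE 0.23) and RUVBL1, an ATPase of chromatin remodellers, at -0.89 (SE 0.12). Target genes of p53 rose in 14 of 28 members and fell in 3 (15 and 3 adjusted over the list alone, median 0.68, camera of limma adjusted p = 0.12). CDKN1A, a cell-cycle inhibitor, was at 2.59 (SE 0.23) and PHLDA3 at 1.90 (SE 0.13).

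A total of 4547 of 22672 genes passed the test with knockdown (limma, adjusted p under 0.05), of which 3909 (86.0%) were higher and 638 lower. Of these, 2032 were also called with the same sign when the recovered reads were tested with voom. The median change of all genes was 0.48, against 0.26 under median-of-ratios scaling and 0.07 under quantile normalization, where 55.6% and 57.4% of calls were higher. On reads that share was 58.5% of 2603 calls, 39.8% with the TPM filter and 44% with quantile normalization. It was 79.8% of 1672 after thinning every library to the depth of the shallowest.

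**Figure D3:**
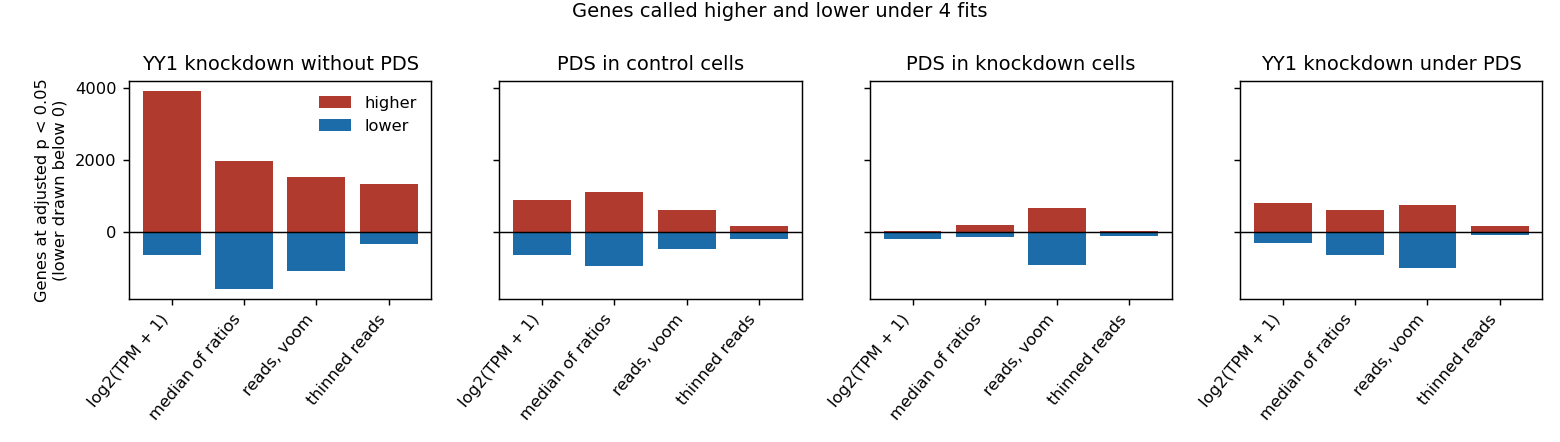
Genes called higher and lower in each comparison under 4 ways of testing: log2 TPM, median-of-ratios scaling, reads with voom weights, and reads thinned to the shallowest library. With knockdown 86.0% of calls on log2 TPM and 55.6% after median-of-ratios scaling were higher.

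The hairpins were also compared with the control one at a time and with each other, to see whether their effects were shared. HSPA5, LGALS3BP, NEFM and MYC had nearly the same TPM under both hairpins. The hairpin shYY1-1 gave 3063 calls (2624 higher, 85.7%) and shYY1-2 gave 3423 (2946 higher, 86.1%) in limma. A total of 2492 genes were called with the same sign for both (2132 higher and 360 lower, against 341 and 9.24 for independent lists) and 0 with opposite signs. The correlation of their log2 changes across genes, which are not independent replicates, was 0.751, and the covariance 0.704. Simulated unchanged groups set against these controls gave 0.706 and 0.514, and a median of 24.5 and a highest of 49 shared calls. With the control libraries divided, replicate 1 for shYY1-1 and 2 for shYY1-2 or the reverse, 1452 and 1453 calls were shared with the same sign and 21 and 25 with opposite signs (simulated highest 20 and 22 shared), and the correlations were 0.239 and 0.229 (simulated 0.07 and 0.067). For the direct difference between hairpins 114 genes passed (limma, 61 higher and 53 lower in shYY1-1, 724 at an unadjusted p under 0.05), of which 0 had 10 reads in 2 libraries. Simulations with no difference gave a median of 46 and a highest of 67 calls, and voom on reads called 5. No gene met the naming rule there. Among protein-coding genes with a mean TPM of at least 5 in either hairpin group, none of which passed, the largest statistics upward belonged to CCDC22 (log2 0.40, SE 0.09, limma adjusted p = 0.27), PXMP2 (0.87), NDUFA8 (0.32), ARC (0.99) and MIIP (0.45). Those downward among the same genes belonged to SRFBP1 (-0.79, SE 0.19, limma adjusted p = 0.32), ARF4 (-0.33), YTHDF3 (-0.38), ETS2 (-0.47) and NRAS (-0.50). Without any single library of shYY1-1 or shYY1-2, the counts of that hairpin and of the difference were lower. Under median-of-ratios scaling 55.7% and 53% of the calls of each hairpin were higher, and on reads 58.9% and 60.4%. Most were lower on reads with the TPM filter (40.9% and 44.9% higher) and with quantile normalization (45.9% and 45.8%).

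PDS in cells with the control hairpin addressed what the ligand does where YY1 is present (2 libraries against 2). HSPA5 fell 9.77-fold, to 316 ± 7.78 TPM (log2 -3.29, SE 0.10, limma adjusted p = 8.5e-06). LGALS3BP fell 10.8-fold, to 28.7 ± 10.5 TPM (log2 -3.43, SE 0.25, limma adjusted p = 0.00038), and MYC fell 2.14-fold, to 82.5 ± 0.97 TPM (log2 -1.10, SE 0.16, limma adjusted p = 0.0074). HIST1H2AE (ENSG00000277075, chromosome 6, 26216975 to 26217483, plus strand), a histone H2A gene, fell 10.2-fold, to 110 ± 46 TPM (log2 -3.35, SE 0.24, limma adjusted p = 0.00036). HSPA8, the constitutive cytosolic heat shock chaperone, rose (log2 1.59, SE 0.10, limma adjusted p = 0.00024), as did SMAD6, an inhibitor of bone morphogenetic protein signalling (log2 1.94, SE 0.11), and NEFM (log2 2.52, SE 0.18).

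The remaining genes named for the largest decreases were CTH (log2 -3.67, SE 0.50), CHAC1 (-3.36, SE 0.71), DDIT3, a transcription factor of the stress response (-3.28, SE 0.41, limma adjusted p = 0.0035), HIST1H2BG (-3.17, SE 0.24) and HERPUD1 (-3.12, SE 0.19). GEM, with 0 reads in shCtrl+PDS, was at least 5.29-fold lower. ASNS was lower with a read ratio of 16.7 (4.07 to 147) and C19orf71 with a ratio of 14.3 (1.98 to 626), while CT45A10 was given no fold. Genes named for the largest increases all had few reads in shCtrl. LTBR was at least 8.61-fold higher, DDN and MLC1 at least 5.67-fold each, PDLIM4 at least 5.25-fold, CD70 at least 4.62-fold, SLC25A43 at least 3.78-fold, UNCX at least 3.15-fold, GBX1 at least 2.31-fold and LGALS2 at least 1.05-fold. SOX21 had a read ratio of 22.7 (3.82 to 921), RAB32 of 12.6 (2.02 to 523) and VAMP8 of 10.1 (1.57 to 423).

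By list, the endoplasmic reticulum and ATF4 genes fell with PDS in control cells as well. In the unfolded protein response 15 of 21 genes fell and 0 rose (17 and 0 adjusted over the list alone, median -1.09, camera of limma adjusted p = 1.0e-22, and adjusted p = 0.058 with an estimated correlation). MANF, a factor resident in the endoplasmic reticulum, was at -2.23 (SE 0.14). Among ATF4 targets 28 of 34 fell (32 adjusted over the list alone, median -1.20, or -1.21 with bounds, camera adjusted p = 4.3e-35, and adjusted p = 0.058 with an estimated correlation). The knockdown and PDS comparisons share the shCtrl libraries, which were the shallowest. In the comparisons that do not use shCtrl the medians of these lists lay between -0.13 and 0.12. Histone genes fell in 39 of 68 members and rose in 4 (41 and 4 adjusted over the list alone, median -0.91, or -0.96 with bounds, camera of limma adjusted p = 6.9e-24, and adjusted p = 0.13 with an estimated correlation). Their share of all reads was 2.32% and 2.43% in the shCtrl libraries and 1.22% and 1.28% in shCtrl+PDS, against 1.89% to 2.06% in the other groups. Replication and E2F targets fell in 10 of 47 members (16, with 2 higher, adjusted over the list alone, median -0.33). MCM6, a replicative helicase subunit, was at -0.80 (SE 0.08). MYC targets fell in 13 of 34 members (17, with 2 higher, adjusted over the list alone, median -0.37) and ribosome biogenesis genes in 9 of 46 (14 adjusted over the list alone, median -0.41). NCL, nucleolin, was at -0.64 (SE 0.10). Adjusted p-values of camera for E2F, MYC and biogenesis genes were 4.9e-08, 7.2e-10 and 1.2e-09 (adjusted p = 0.31, adjusted p = 0.31 and adjusted p = 0.27 with an estimated correlation). Of the cytosolic ribosomal proteins 15 fell and 2 rose (23 and 5 adjusted over the list alone, median -0.11, camera of limma adjusted p = 0.00018, and adjusted p = 0.75 with an estimated correlation), and the direction flipped under quantile normalization (median 0.08). On reads with an estimated correlation the lists of this paragraph passed, with adjusted p from 0.00035 to 0.027 (camera of limma), except the ribosomal proteins (adjusted p = 0.060).

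Heat shock genes rose in 6 of 18 members and fell in 1 (8 and 1 adjusted over the list alone, median 0.30, camera of limma adjusted p = 0.014, and adjusted p = 0.48 with an estimated correlation). HSPA8, HSPB1 (log2 1.60, SE 0.22) and BAG3, a co-chaperone (1.24, SE 0.22), were among them. Genes of the TGF-beta response and epithelial-mesenchymal transition rose in 5 of 25 members (10, with 1 lower, adjusted over the list alone, median 0.65, or 0.64 with bounds, camera of limma adjusted p = 0.00014, and adjusted p = 0.27 with an estimated correlation). SPARC, a matrix glycoprotein, was at 3.24 (SE 0.42). Mitotic genes rose in 8 of 52 members (10 adjusted over the list alone, median 0.19, camera of limma adjusted p = 0.043, and adjusted p = 0.75 with an estimated correlation). Inflammatory genes of the NF-kappaB pathway rose in 2 of 15 (3 adjusted over the list alone, median 0.74, or 0.40 with bounds, camera of limma adjusted p = 0.049, and adjusted p = 0.31 with an estimated correlation). The 10 tested markers of epithelial carcinoma cells, a cell type other than the line studied, had a median of 0.80, or 0.77 with bounds. Of these 0 were called (0 adjusted over the list alone, camera of limma adjusted p = 0.043, and adjusted p = 0.27 with an estimated correlation). Among 23 oncogenes with a promoter G-quadruplex MYC and VEGFA (log2 -1, SE 0.15) fell and 2 rose. PDGFA was at least 1.05-fold higher, and the list did not pass (camera of limma, adjusted p = 0.56). On reads with an estimated correlation the TGF-beta list passed (camera of limma, adjusted p = 0.027) and the heat shock, mitotic, NF-kappaB and carcinoma lists did not (adjusted p = 0.17, 0.51, 0.51 and 0.47).

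Under PDS in control cells 1533 of 22672 genes passed (limma, 890 higher, 58.1%, and 643 lower), and 857 of them were also called on reads. The median change of all genes was 0.00, and 69.0% of 2100 calls were higher when TPM were rescaled without short noncoding and histone genes. Fitting only the groups compared gave 90 calls (27.8% higher) and thinning 367 (48.5%), so that the majority turned in these.

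PDS in cells with a hairpin against YY1 addressed what the ligand does where YY1 is depleted (4 libraries against 4, none of them shCtrl). KRT8 (ENSG00000170421, chromosome 12, 52897187 to 52949954, minus strand), a keratin of simple epithelia, rose 3.05-fold, from 14.6 ± 2.72 and 14.4 ± 2.32 TPM to 47.4 ± 4.19 and 45.3 ± 10.8 TPM (log2 1.61, SE 0.15, limma adjusted p = 0.0067). LTBR fell 7.53-fold, from 11.7 ± 0.738 and 12.5 ± 0.365 TPM to 0.322 ± 0.116 and 1.31 ± 0.425 TPM (log2 -2.91, SE 0.29, limma adjusted p = 0.0067). In the same direction COL2A1 (ENSG00000139219, chromosome 12, 47972965 to 48004554, minus strand), a fibrillar collagen gene, fell 3.47-fold (log2 -1.80, SE 0.18, limma adjusted p = 0.0067).

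The other genes named for increases were HOXB3 (log2 1.12, SE 0.18), KIF1A, an axonal motor (1.06, SE 0.17), VEZF1 (1.01, SE 0.18), LSR (0.87, SE 0.09), AEBP2 (0.78), DDX42 (0.76, SE 0.08), JPH1 (0.68), CA2 (0.67), EXOC3 (0.66), ILRUN (0.60) and TRMT61A (0.60), all with limma adjusted p from 0.0067 to 0.049. Those named for decreases were SFRP2, a secreted WNT antagonist (-2.69, SE 0.32, on 4 reads with PDS against 57), METTL7B (-1.56, SE 0.22), MXRA8 (-1.40), DPYSL3 (-1.40, SE 0.14), LRATD2 (-1.28), RCOR2 (-1.27), BTN3A1 (-1.27), ASPHD1 (-1.24) and FAM78A (-1.21), with limma adjusted p from 0.0067 to 0.049. MYC fell (log2 -0.65, SE 0.11, limma adjusted p = 0.047) and CCND1, cyclin D1, fell (-1.05, SE 0.15, limma adjusted p = 0.019), the 2 of 23 promoter G-quadruplex oncogenes called here.

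The unfolded protein response and ATF4 targets, which fell in the comparisons against shCtrl, had 0 called members here and medians of -0.13 and -0.10 against -0.20 for all genes (camera of limma, adjusted p = 0.73 and 0.60). A total of 8 lists passed with the preset correlation and none with an estimated one, on log2 TPM or on reads. Genes of cholesterol synthesis fell in 2 of 24 members, SQLE (-0.97, SE 0.10) among them, with 3 adjusted over the list alone and a median of -0.23. Hypoxia genes fell in 2 of 31, NDRG1 (-0.70, SE 0.10) and LDHA (-0.48, SE 0.07), with 5 adjusted over the list alone and a median of -0.30. Both lists had camera adjusted p = 0.029, and adjusted p = 0.78 with an estimated correlation. Nuclear genes of oxidative phosphorylation fell in 2 of 94 members (3 adjusted over the list alone, median -0.20) and heat shock genes in 0 of 18 (2 adjusted over the list alone, median -0.20). Mitotic genes fell in 2 of 52 (5 adjusted over the list alone, median -0.16) and ribosomal proteins in 1 of 82 (8 adjusted over the list alone, median -0.12). Each of these 4 tests pointed down (camera adjusted p = 0.029, and adjusted p = 0.78, 0.78, 0.85 and 0.93 with an estimated correlation), although the mitotic and ribosomal protein medians lay 0.04 and 0.08 above that of all genes. Under median-of-ratios scaling the ribosomal protein list passed in the upward direction (median 0.05, camera of limma adjusted p = 2.2e-05), and the heat shock and mitotic tests pointed up without passing (adjusted p = 0.98 and 0.90). The 47 replication and E2F targets pointed up with 2 members lower (2 adjusted over the list alone, median -0.01, mean -0.05, camera adjusted p = 0.047, and adjusted p = 0.90 with an estimated correlation). The markers of epithelial carcinoma cells passed with KRT8 alone called among 10 (1 adjusted over the list alone, median 0.10, camera adjusted p = 0.029, and adjusted p = 0.77 with an estimated correlation).

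In knockdown cells PDS gave 218 calls (limma, 38 higher, 17.4%, and 180 lower), of which 105 were also called on reads, and the median change of all genes was -0.20. Of the 218, 106 had 10 reads in 2 libraries. Simulations with no change gave a median of 31.5 and a highest of 55 calls in this comparison. The share of higher calls was 61.2% of 340 under median-of-ratios scaling, 45.7% under quantile normalization, 46.4% after rescaling, 41.8% of 1575 on reads and 52.9% of 1371 on reads with quantile normalization. The count was lower without any single library. PDS in control cells gave more calls on log2 TPM (1533) but fewer on reads (1074 against 1575), so counts do not rank the effects. Voom recovered 83% of simulated 2-fold changes here and 25% in control cells (main test 43% and 19%).

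Knockdown under PDS addressed the effect of YY1 where the ligand is present (4 libraries against the 2 of shCtrl+PDS). TUBA1A (ENSG00000167552, chromosome 12, 49184796 to 49189324, minus strand), an alpha-tubulin, had 71 ± 7.41 TPM in shCtrl+PDS and 13 ± 1.87 and 13.3 ± 3.34 TPM in the knockdown groups, a 5.12-fold fall (log2 -2.35, SE 0.30, limma adjusted p = 0.0063). LTBR fell 7.34-fold from 12.6 ± 6.68 TPM (log2 -2.88, SE 0.35, limma adjusted p = 0.0049). METTL7B fell 6.32-fold from 28.9 ± 5.82 TPM (log2 -2.66, SE 0.26, limma adjusted p = 0.0027) and MYC 2.35-fold (log2 -1.23, SE 0.14, limma adjusted p = 0.0040). SLC2A3, the neuronal glucose transporter, rose 5.74-fold from 3.55 ± 2.04 TPM to 23.9 ± 2.61 and 23.7 ± 1.15 TPM (log2 2.52, SE 0.46, limma adjusted p = 0.022). AP3B2, a neuronal adaptor subunit, rose 4.81-fold (log2 2.27, SE 0.30, limma adjusted p = 0.0070).

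Further genes named for increases were TMEM128 (log2 2.15, SE 0.35) and WFIKKN1 (2.11, SE 0.30). For those with few reads in shCtrl+PDS the read ratios were 10.7 for NFKBIL1 (1.81 to 432), 10.4 for VSTM2L (1.76 to 421), 9.89 for RUNDC3A (2.65 to 83.2), 8.33 for C19orf71 (1.39 to 339) and 6.77 for NPIPB15 (1.11 to 277), a member of a family of near-identical copies. CAMK2N2 was at least 1.65-fold higher and PVALEF at least 1.48-fold, and ALKAL1 also had 0 reads in shCtrl+PDS. Further decreases were those of SFRP2 (-2.50, SE 0.40), PCDHGC3 (-2.43, SE 0.40), GALNT14 (-2.35, SE 0.45), SLC35D3 (-2.23, SE 0.35) and PLP2 (-2.03, SE 0.47). RAB38 was lower with a read ratio of 26.9 (3.45 to 1210) and UTF1 with one of 7.68 (1.64 to 47.5), and TEX53 and LKAAEAR1 were given no fold.

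Histone genes rose in 38 of 68 members and fell in 1 in this comparison (49 and 1 adjusted over the list alone), with HIST3H2BB at 1.18 (SE 0.10). Their median was 0.66, or 0.73 with bounds (camera of limma, adjusted p = 9.4e-24, and adjusted p = 0.12 with an estimated correlation). Target genes of p53 rose in 6 of 28 members (11 adjusted over the list alone, median 0.60, camera of limma adjusted p = 8.9e-07, and adjusted p = 0.12 with an estimated correlation). PHLDA3 was at 1.45 (SE 0.13) and GADD45A, a growth arrest gene, at 1.28 (SE 0.15). Mitotic genes rose in 10 of 52 members (18 adjusted over the list alone, median 0.39), with KIF23 at 0.92 (SE 0.12). Replication and E2F targets rose in 9 of 47 (16, with 2 lower, adjusted over the list alone, median 0.22), with E2F1 at 0.66 (SE 0.11). Cohesin and CTCF genes rose in 5 of 16 (8 adjusted over the list alone, median 0.57), with STAG2 at 0.93 (SE 0.12). Lysosome genes rose in 10 of 42 and fell in 1 (16 and 1 adjusted over the list alone, median 0.40), with LAMP1 at 0.87 (SE 0.12). Camera adjusted p-values of these 4 were 8.9e-07, 0.0015, 3.7e-05 and 0.00021 (adjusted p = 0.36, 0.59, 0.35 and 0.36 with an estimated correlation). Neuronal genes rose in 5 of 23 (5 adjusted over the list alone, median 0.61, or 0.51 with bounds), with SYP, synaptophysin, at 1.97 (SE 0.16). Immediate early genes rose in 5 of 31 (10, with 1 lower, adjusted over the list alone, median 0.39, or 0.40 with bounds). Camera of limma gave these adjusted p = 0.00022 and 0.014, and adjusted p = 0.12 and 0.36 with an estimated correlation. HOX genes rose in 2 of 38 (6 adjusted over the list alone, median 0.35). Polycomb and DNA methylation enzymes rose in 1 of 29 (1 adjusted over the list alone, median 0.29) and homologous recombination genes in 1 of 34 (5 adjusted over the list alone, median 0.25). Their camera adjusted p-values were 0.0080, 0.020 and 0.030 (adjusted p = 0.12, 0.54 and 0.36 with an estimated correlation). On reads with an estimated correlation histone, p53, lysosome and neuronal genes passed (camera of limma, adjusted p = 0.016, 0.035, 0.035 and 0.049), and the other lists of this paragraph had adjusted p from 0.16 to 0.48.

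In the downward direction under PDS, cholesterol genes fell in 3 of 24 members and rose in 1 (3 and 1 adjusted over the list alone, median -0.20, or -0.34 relative to all genes), with SQLE at -0.95 (SE 0.12). Glycolysis genes fell in 4 of 19 and rose in 1 (6 and 1 adjusted over the list alone, median -0.17), with PFKP at -1.13 (SE 0.14) and LDHA at -0.54 (SE 0.09). Ribosomal proteins fell in 6 of 82 and rose in 1 (7 and 1 adjusted over the list alone, median -0.06), with RPL3 at -0.66 (SE 0.07). MYC targets fell in 4 of 34 and rose in 3 (5 and 3 adjusted over the list alone, median -0.11), and hypoxia genes fell in 2 of 31 and rose in 2 (4 and 2 adjusted over the list alone, median -0.17). In this order the camera test of limma gave adjusted p = 0.00042, 0.00042, 0.0041, 0.020 and 0.030, and adjusted p = 0.35, 0.36, 0.69, 0.69 and 0.41 with an estimated correlation. On reads with an estimated correlation these were 0.035, 0.033, 0.016, 0.049 and 0.19, with 33 ribosomal protein genes lower and 3 higher. HSPA5 fell here too (log2 -0.63, SE 0.09, limma adjusted p = 0.0082), as did PDIA6 (-1.48, SE 0.11). The unfolded protein response list (3 of 21 lower, median 0.12) and the ATF4 targets (5 of 34 higher and 4 lower, median 0.05) did not pass (camera of limma, adjusted p = 0.64 and 0.44).

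Under PDS 1100 genes passed with knockdown (limma, 796 higher, 72.4%, and 304 lower), 790 of them also on reads, and the median change of all genes was 0.14. The share of higher calls was 48.4% of 1257 under median-of-ratios scaling, 54.4% under quantile normalization, 60.7% after rescaling and 42.9% of 1764 on reads. Without any single library other than those of shCtrl the count was lower.

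**Figure D4:**
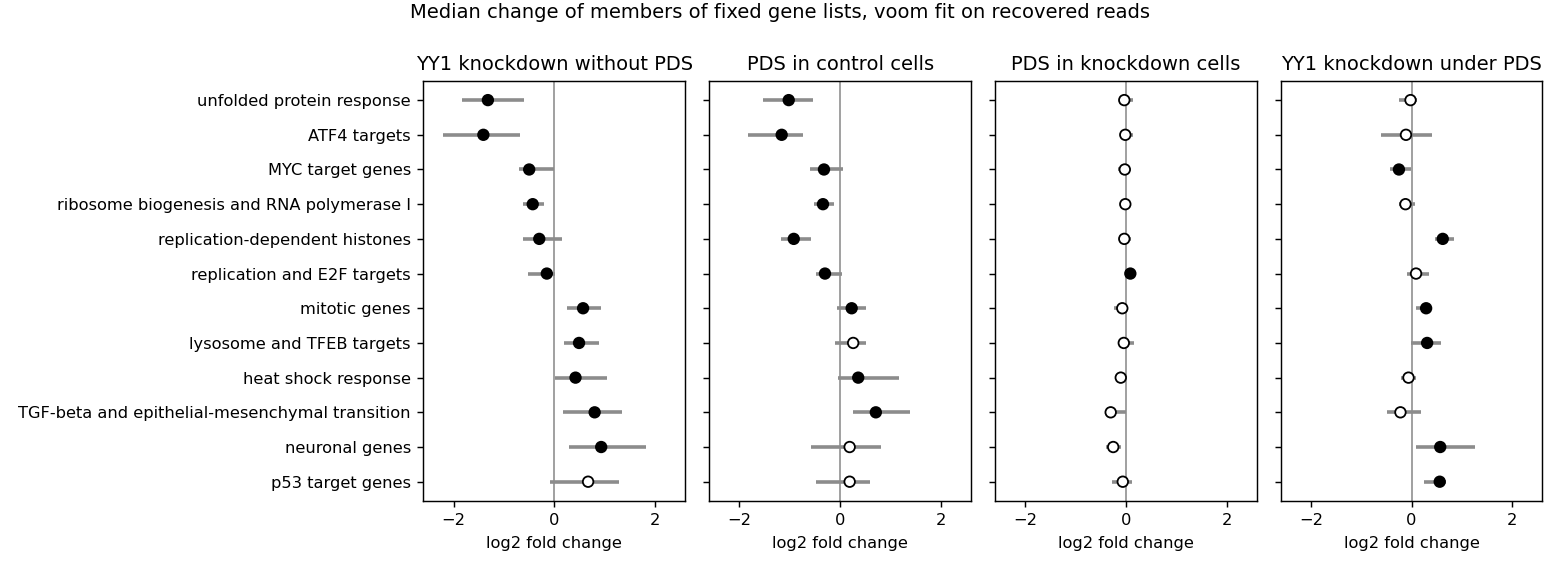
Median log2 change of 12 gene lists in 4 comparisons, tested on the recovered reads with voom weights. Bars are the interquartile range of members, and filled points have a camera adjusted p under 0.05 with the preset correlation.

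The interaction of knockdown with PDS tested directly whether the ligand acted differently in control and knockdown cells. HSPA5 had a PDS effect higher by 3.24 (log2, SE 0.13, limma adjusted p = 3.0e-05) in knockdown than in control cells, where it had fallen 9.77-fold. Its level was 210 ± 13.3 and 197 ± 3.58 TPM in the knockdown groups with PDS. The PDS effect was also higher in knockdown cells for HIST1H2AE (log2 3.77, SE 0.30, limma adjusted p = 0.00076) and HERPUD1 (3.21, SE 0.23, limma adjusted p = 0.00075). LTBR had an interaction of -6.58 (SE 0.49, limma adjusted p = 0.00075), a size that depends on the pseudocount because shCtrl had 0 reads. It went from 0 to 12.6 ± 6.68 TPM with PDS in control cells and from 11.7 ± 0.738 and 12.5 ± 0.365 to 0.322 ± 0.116 and 1.31 ± 0.425 TPM in knockdown cells. Among lists, the unfolded protein response had 12 of 21 genes with a positive interaction (16 adjusted over the list alone, median 1.19, camera of limma adjusted p = 4.5e-24, and adjusted p = 0.050 with an estimated correlation). ATF4 targets had 23 of 34 (29 adjusted over the list alone, median 1.17, camera of limma adjusted p = 3.3e-37, and adjusted p = 0.050 with an estimated correlation). The interaction of MYC was 0.45 (SE 0.20, limma adjusted p = 0.25) and that of YY1 0.03 (SE 0.17, limma adjusted p = 0.96).

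A total of 1211 genes passed the interaction test (limma, 303 positive, 25%, and 908 negative), 756 of them also on reads, with a median over all genes of -0.29. Positive shares were 49.2% under median-of-ratios scaling, 42.4% under quantile normalization and 38.3% of 1265 on reads. The count was lower without any single library but those of shCtrl.

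Averaged over PDS, knockdown gave 4358 calls in limma (3673 higher, 84.3%, and 685 lower), and PDS averaged over all cells gave 468 (114 higher, 24.4%, and 354 lower). Under median-of-ratios scaling 54.6% and 55.1% of these calls were higher, under quantile normalization 58.2% and 51.8%, and after rescaling the PDS share was 56.5%. On reads 59.5% and 53.4% were higher, with the TPM filter 35.3% of 4816 and 50.1%, and with quantile normalization 48.4% and 55.1%. The PDS count was lower without any single knockdown library.

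The genes called with knockdown and with PDS in control cells overlapped. HSPA5, LGALS3BP, MYC, CTH, CHAC1 and HERPUD1 fell in both comparisons, and NEFM rose in both. A total of 1103 genes were called with the same sign (772 higher and 331 lower, against 153 and 18.1 for independent lists), and 10 with opposite signs. Simulated unchanged groups with the same controls, limited as above, shared a median of 25 and a highest of 48 calls. The correlation of the changes across genes was 0.669, against 0.648 in the simulation, and the covariance 0.586 against 0.463. With the control libraries divided, replicate 1 for knockdown and 2 for PDS or the reverse, 671 and 750 calls were shared with the same sign and 42 and 62 with opposite signs (simulated highest 21 for each), and the correlations were 0.156 and 0.144 (simulated 0.019 and 0.024). On reads 310 and 295 were shared (simulated highest 0 for each). Both control libraries still come from the shCtrl group. Pairs of comparisons with no library in common (shYY1-1 against shCtrl with PDS in shYY1-2 cells, and the reverse) shared 7 and 5 calls with the same sign and 27 and 22 with opposite signs, with correlations of -0.066 and -0.069. On reads these pairs shared 79 and 81 calls with the same sign (28.2 higher and 18.9 lower, and 31.5 and 17.2, for independent lists) and 158 and 147 with opposite signs. These pairs test PDS only in knockdown cells, so they cannot show whether PDS in control cells resembles knockdown. Any state that the hairpin groups without PDS share enters their comparisons with opposite signs. Knockdown without and under PDS, which share no library either, had 554 calls of the same sign and 83 of opposite signs (simulated highest 15). Independent lists would share 137 higher and 8.55 lower, and the correlation was 0.103 (simulated 0.065). On reads 647 and 138 calls had the same and opposite signs (independent lists 93.7 higher and 88.4 lower). The correlation there was 0.192 (simulated -0.006). Agreement across genes was thus weak. The 7 were AC009065.8, ARF4, CRABP2, DDX42, MCM6, PNKDP1 and RNA5SP462. The 5 were AL732292.2, DDX42, NDUFA8, QPCTL and SNORA9B, and all of these were chosen after their values were seen. Without replicate 1 or 2 of shCtrl+PDS the overlap was 608 or 521.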

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

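The tests of depth, of a state shared by the shCtrl cultures, of short RNA loss and of S phase were chosen only after the results they bear on were seen. All values in the next paragraph are differences of the PDS effect between knockdown and control cells (log2, interaction in limma), which is what marks them for a closer look.

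The PDS effect differed between control and knockdown cells for 1211 genes, a count that leaving out 1 library lowered by over 1.5 times for 9 of the 12 libraries, all but both of shCtrl and replicate 2 of shYY1-2+PDS (lowest 532, without shYY1-2 replicate 1). It was higher in knockdown cells for HIST1H2AE (3.77), CTH (3.53), HIST1H2BG (3.25), HSPA5 (3.24), HERPUD1 (3.21) and FBXL16 (3.19). It was lower for LTBR (-6.58), SFRP2 (-5.90), RAB38 (-5.05), RAMP2 (-5.01), GALNT14 (-4.70) and PCDHGC3 (-4.66), which had 0 or 1 reads in shCtrl, so that these sizes depend on the pseudocount. Lists with a higher median in knockdown cells were the unfolded protein response (1.19), ATF4 targets (1.17), histones (0.78), replication and E2F targets (0.33), MYC targets (0.25), ribosome biogenesis (0.25) and cytosolic ribosomal proteins (0.02, and -0.14 under quantile normalization), against a median of -0.29 for all genes. Of the lists with a lower median, those flagged were TGF-beta genes (-1.09), heat shock (-0.52) and mitotic genes (-0.42). With an estimated correlation the unfolded protein response and ATF4 targets kept adjusted p = 0.050, and the other 8 lists had adjusted p from 0.12 to 0.89 (camera of limma). On reads with an estimated correlation all 10 but heat shock and mitotic genes passed, with adjusted p from 0.00050 to 0.045, and 0.14 and 0.48 for those (camera of limma).

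Most calls of knockdown without PDS were higher (86% of 4547). What lower depth of the shCtrl libraries would give was partly seen: with no change simulated at the real depths a median of 55.5 of 61.5 calls were higher, and in the fit on reads the share fell to 58.5%. After thinning all libraries to 1 depth 79.8% of 1672 calls were still higher, which argues against depth as the whole cause, and after rescaling without short noncoding RNA the share was 78.6%, which argues against a different share of those RNAs. Median-of-ratios scaling alone moved it to 55.6%, and most calls were lower on reads with quantile normalization (44%) and with the TPM filter (39.8%), which change the test and the genes as well. How far depth, scaling and the test make the excess stays open, and so does an excess of increases after YY1 loss.

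The unfolded protein response and ATF4 targets fell both with knockdown and with PDS in control cells. Of their members called lower, at least 53.5% were also called lower on reads and after thinning to 1 depth, in both comparisons, and at least 79.1% without either shCtrl library, which argues against depth or a single library as the whole cause. In PDS in knockdown cells and knockdown under PDS, which do not use shCtrl without PDS, the medians of both lists lay within 0.13 of 0, the farthest at -0.13. A candidate explanation is a state of the shCtrl cultures, with high HSPA5 (3100 TPM against 197 to 316 in the other groups), that both comparisons share, and these values are what it needs. A response to YY1 loss and to PDS that does not add up is not excluded, since both readings rest on the same 2 shCtrl libraries.

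Histone genes fell with PDS in control cells, where shCtrl+PDS libraries held 1.22% and 1.28% of their reads in them and all other libraries 1.89% to 2.43%. Reads moving between near-identical copies would leave the sum level, but the highest share in shCtrl+PDS lay below the lowest in shCtrl (difference -1.04 points), which argues against that. Loss of short RNA would lower snoRNA and snRNA genes too, but the median change of 31 such genes on reads was 0.43 (quartiles -0.01 and 0.98, histones -0.92), which argues against it. Fewer cells in S phase could account for it, and cannot be told apart from a culture difference: replication and E2F targets passed as a list on reads with an estimated correlation (camera of limma, adjusted p = 0.027, 11 lower and 1 higher) but not on log2 TPM (adjusted p = 0.31). An effect of PDS itself on histone transcripts stays open, untested in other control cells.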

How the results depend on the processing

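The tests on reads with voom, on thinned reads, on the overlap of knockdown without and under PDS and with divided control libraries were chosen only after the depths were seen. The overlap of a hairpin against shCtrl with PDS in cells of the other hairpin was planned beforehand. Of 111 named genes 109 kept their call under median-of-ratios scaling, 108 under quantile normalization, 96 at a pseudocount of 0.1, 74 with only the groups compared, 93 on reads (16 not measured there) and 52 after thinning, and none of them reversed. Of 61 list calls 45 kept theirs under median-of-ratios scaling, 50 under quantile normalization, 48 on reads and 43 after thinning. With an estimated correlation 4 lists passed, and 33 on reads. Depth limits all comparisons with shCtrl, since thinning to its level also removes reads from every other group. Unless stated, the cause of a change below was not tested.

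Knockdown without PDS (4547 calls) gave 2603 on reads, 2559 on reads with quantile normalization and 1672 after thinning, which on simulated data recovered 9% of 2-fold and 42% of 4-fold changes against 36% and 83% at full depth. Thinning gave 922 calls for shYY1-1 (3063), 1120 for shYY1-2 (3423), 287 for the interaction (1211) and 1837 for knockdown averaged over PDS (4358).

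The hairpin difference (114) gave 178 calls with no filter, 191 with no trend, 60 with the robust option, 0 at 5 TPM and 0 with only the groups compared (limma, 724 at an unadjusted p under 0.05 in the main test), 5 on reads, 6 on reads with the TPM filter and 2 on reads with quantile normalization. The 5 were ACTB, EEF2, FLNA, RPS2 and SNORD3A and the 2 were HSP90AA1 and MALAT1, chosen after their values were seen.

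PDS in control cells (1533) gave 890 calls with no trend, 90 with only the groups compared, 753 on reads with the TPM filter, 963 on reads with quantile normalization and 367 after thinning. PDS in knockdown cells (218) gave 67 at 5 TPM, 340 under median-of-ratios scaling, 119 with the robust option, 140 with only the groups compared, 1575 on reads, 1147 with the TPM filter, 1371 with quantile normalization and 135 after thinning. Knockdown under PDS (1100) gave 431 with no trend, 449 with only the groups compared, 1764 on reads, 1671 with quantile normalization and 268 after thinning. PDS averaged over cells (468) gave 1070, 793 and 1054 in the 3 fits on reads and 233 after thinning.

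The overlap of knockdown and PDS (1103) was 676 with no trend, 77 with only the groups compared, 596 on reads with the TPM filter, 727 with quantile normalization and 269 after thinning, 7 and 5 between comparisons that share no library, and 211 between the averages. Between the averages 107 further calls had opposite signs. With 1 shCtrl library for each comparison it was 671 and 750, and 310 and 295 on reads, where fewer control libraries entered each comparison.

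Replicate numbers share only a number: correlations of same-numbered deviations over 15 pairs of groups ran from -0.029 to 0.024. With that number as a replicate block the hairpin difference gave 71 calls and PDS in knockdown cells 107, and 103 of 111 named genes and 60 of 61 list calls were kept.

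Results that reversed, each given as the list's median or gene's log2 change: histones with knockdown, 0.06 under quantile normalization. Ribosomal proteins with PDS in control cells, 0.08 under quantile normalization and 0.06 on reads with it. Ribosomal proteins with PDS in knockdown cells, 0.05 under median-of-ratios scaling (passing upward, camera of limma adjusted p = 2.2e-05; 0.084 to 0.25 where the others reversed), 0 rescaled, -0.01 on reads and -0.02 with the TPM filter. Mitotic (0.01) and heat shock genes (-0.03) with PDS in knockdown cells, under median-of-ratios scaling. Ribosomal proteins in the interaction, -0.14 under quantile normalization (passing downward, camera of limma adjusted p = 0.0098) and -0.08 on reads with it. RNU5A-1 with knockdown under PDS was 0 after thinning, RNU7-143P -0.26 on reads with the TPM filter, MYBL2 with knockdown -0.01 under median-of-ratios scaling, and the interaction of YY1 -0.17 after thinning.

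Leaving out 1 library, with the lone library of its group assumed to vary like the others, gave 2891 (without shYY1-1 replicate 1) to 4706 calls for knockdown, 914 to 3159 for shYY1-1 (1365 without its replicate 2), 1175 to 3637 for shYY1-2 (1176 without its replicate 2) and 3237 to 4180 for knockdown averaged over PDS. The hairpin difference ran from 0 without either shYY1-1 library to 137, with 23 and 14 without shYY1-2 replicates 1 and 2 (limma). PDS in control cells ran from 718 to 1737, with 848 and 718 without shCtrl+PDS replicates 1 and 2. PDS in knockdown cells ran from 60 (shYY1-1 replicate 2) to 155, lower by over 1.5 times for 10 of the 12 libraries, all but replicate 2 of shCtrl and of shCtrl+PDS. Knockdown under PDS ran from 389 (shCtrl+PDS replicate 2) to 1432, lower by over 1.5 times without either library of shYY1-2, shCtrl+PDS or shYY1-2+PDS or replicate 2 of shYY1-1+PDS. The interaction ran from 532 to 1433 and PDS averaged over cells from 162 (shYY1-1 replicate 1) to 648, lower by over 1.5 times for each of the 8 knockdown libraries. List calls ran from 47 to 61, the overlap from 521 to 1324 (608 and 521 without shCtrl+PDS replicates 1 and 2), YY1 from -1.66 to -1.61 and its interaction from -0.07 to 0.13. Planned motif windows, loops and the longer YY1 motif were not run, for want of a genome sequence here.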

Other observations

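Among the motif tests, those other than G-quadruplex motifs with PDS in knockdown cells and YY1 motifs with knockdown without PDS were chosen only after the result was seen, as were the shares of called genes with a motif and the divisions that keep the libraries of a group together.

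The lists in this paragraph and the next did not pass as lists with knockdown without PDS. With knockdown HOX genes rose in 14 of 38 members and fell in 2 (20 and 2 adjusted over the list alone, median 0.75, or 0.56 with genes at 0 reads set to their bound, camera of limma adjusted p = 0.27). HOXD13 was at 1.60 (SE 0.15). Zinc-finger genes rose in 65 of 435 members and fell in 3 (63 and 2 adjusted over the list alone, median 0.41, or 0.34 with bounds, camera of limma adjusted p = 0.79). The spliceosome (9 of 43 higher and 4 lower, 10 and 4 adjusted over the list alone, median 0.22, or 0.16 with bounds), the proteasome (14 of 35 and 2, 16 and 2 adjusted over the list alone, median 0.48, or 0.45 with bounds) and nuclear genes of oxidative phosphorylation (18 of 94 and 6, 25 and 6 adjusted over the list alone, median 0.34, or 0.26 with bounds) did not pass either. Their camera adjusted p-values in limma were 0.76, 0.24 and 0.78. PSMA7 (-1.10, SE 0.15) and PSMD13 (-1.14, SE 0.20) fell, against 14 called members that rose. Among abundant noncoding RNAs (6 of 19 higher and 3 lower, 6 and 5 adjusted over the list alone, median 0.08, camera of limma adjusted p = 0.67) NEAT1 rose with knockdown (1.70, SE 0.11) and MALAT1 rose (1.63, SE 0.10). With PDS in knockdown cells NEAT1 fell (-0.95, SE 0.09, limma adjusted p = 0.0067) and MALAT1 fell (-0.77, SE 0.08, limma adjusted p = 0.0067).

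Other lists with knockdown, none of which passed, were mitochondrial ribosomal proteins (11 of 75 higher and 3 lower, 10 and 2 adjusted over the list alone, median 0.07), the TCA cycle and mitochondrial biogenesis (4 of 27 and 2, 8 and 4 alone, median 0.25), homologous recombination (7 of 34 and 1, 11 and 1 alone, median 0.41), cholesterol synthesis (3 of 24 and 2, 3 and 2 alone, median -0.07) and hypoxia (8 of 31 and 3, 8 and 3 alone, median 0.29). Signalling lists were NF-kappaB (5 of 15 higher, 5 alone, median 0.95, or 0.46 with bounds), YAP and TEAD (7 of 20 and 1 lower, 9 and 1 alone, median 0.58), WNT (3 of 15, 3 alone, median 0.78, or 0.65 with bounds) and interferon-stimulated genes (1 of 22, 0 alone, median 0.30, or 0.18 with bounds). Polycomb and DNA methylation enzymes (9 of 29 higher and 2 lower, 11 and 2 alone, median 0.53), telomere genes (2 of 14, 2 alone, median 0.01) and housekeeping genes (5 of 16 and 3 lower, 6 and 3 alone, median 0.12) did not pass either. Markers of other cell types were fibroblast and smooth muscle (3 of 10 higher, 4 alone, median 0.58, or 0.27 with bounds), leukocyte (1 of 7, 1 alone, median 0.84, or 0.47 with bounds), epithelial carcinoma (1 of 10, 0 alone, median 1.14, or 0.11 with bounds) and kidney and adrenal lineage (1 of 8, 1 alone, median 0.66, or 0.35 with bounds). Of snoRNA and snRNA genes 34 of 231 were called higher and 2 lower (29 and 2 adjusted over the list alone), with a median of 1.56 that is 0 with bounds, and 133 of them allowed no fold. Adjusted p-values of camera in limma for the lists of this paragraph lay between 0.054 (cholesterol) and 0.95 (housekeeping).

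Whether other divisions of the libraries would give as many calls was tested in models without an interaction term, so that counts differ from those above. With both libraries of a group kept together, PDS in knockdown cells allows 2 divisions (230 calls for the real one, 3 for the other) and knockdown averaged over PDS 15 (3609 for the real one, a highest of 3820 for the others), too few for a share under 0.05. The division with 3820 set shYY1-1 and shYY1-2 without PDS against all other groups. With PDS in the model it compares these only with shCtrl, which is knockdown without PDS itself, so it shows no structure beyond knockdown. With single libraries as the units the highest others gave 8 and 89 calls, and 1 of 34 and 1 of 100 divisions, the real one itself, gave as many. Those numbers decide nothing, since divisions that part the libraries of a group count group differences as spread, which lowers their calls. For PDS averaged over all cells the real division gave 28 calls, 8 of 100 gave as many, and the highest gave 1377. The 1377 came with shCtrl, shYY1-1 and shYY1-1+PDS set against the other groups. With the hairpin in the model that division compares only shCtrl with shCtrl+PDS, which is PDS in control cells itself. A division that holds a PDS effect cannot measure chance, so chance is neither shown nor excluded.

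A hypothesis was that PDS lowers transcripts with a G-quadruplex motif near their start. Of 19368 protein-coding genes with a long enough transcript 4227 had a motif in the first 500 bases, as runs of G or of C. Runs of C alone put the motif on the opposite DNA strand and not in the transcript. With PDS in knockdown cells the median of the 2878 tested on reads lay at percentile 46 of 10000 random lists matched on GC content and expression (median -0.06, central 95% of matched lists -0.069 to -0.051). Matched lists were drawn from all tested genes, those with the motif included, which pulls them toward the motif genes. The 8320 genes without the motif had a median of -0.082, unmatched. Neither value favours the hypothesis. Tested afterwards, the genes with a G-quadruplex motif lay at percentile 100 with PDS in control cells (median 0.206, matched 0.12 to 0.163, camera of limma adjusted p = 0.12) and with knockdown (0.268, matched 0.172 to 0.219, camera of limma adjusted p = 0.34), and at percentile 85 with knockdown under PDS. A second hypothesis was that knockdown changes the 581 tested genes with a YY1 motif in the first 200 bases. Their median lay at percentile 85.5 with knockdown (0.202, matched 0.122 to 0.229), which changes in both directions would not move. Of them 18.6% were called higher (matched 13.3% to 18.8%, percentile 96.3; other genes 12.8%) and 9% lower (matched 8.3% to 12.7%, percentile 8.3; other genes 8.9%). Of the genes with a G-quadruplex motif 16.5% were called higher (matched 13% to 14.9%) and 8.4% lower with knockdown (matched 9.1% to 10.8%), and 7.9% higher (matched 6% to 7.3%) and 3.4% lower with PDS in control cells (matched 3.5% to 4.6%). Tested afterwards, the median of the genes with a YY1 motif lay at percentile 45.1 with PDS in control cells, 100 with PDS in knockdown cells (-0.018, matched -0.076 to -0.034, camera of limma adjusted p = 0.28) and 99.9 with knockdown under PDS (0.103, matched 0.013 to 0.079, camera of limma adjusted p = 0.12). Random lists take genes as independent, which makes extreme percentiles too easy to reach when genes vary together. Camera, which allows for correlation (preset 0.01) and was adjusted over the 8 tests, passed for none of the medians (adjusted p from 0.12 to 0.73 in limma). An effect of either motif is left open.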
